A study of Mus musculus with 9 samples.

How the data were processed

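Total RNA from mouse brain was sequenced in 9 libraries of a haemorrhage study, 3 in each of a control, an experimental and an intervention group. Per the labels, the tissue lay around the haematoma, but whether the control had a haemorrhage is not given in the sources used here. Per the labels' protocols, RNA was purified with a Qiagen RNeasy kit, libraries were made with a SMARTer mRNA-seq kit, and the series names an Illumina NovaSeq as the instrument. The deposited table holds 1 FPKM value per gene and library, per the file headers. Per the labels, the genome build was mm10. The aligner, the counting tool and the gene annotation are not given in the sources used here, and no steps of single reads were redone. In 97.7% of 13517 values tested, the gene value multiplied by the length of its joined exons was whole in millionths (tolerance 0.01), against 1.99% with a length 1 base longer, so that gene values follow from transcript values weighted by length. The table gives no counts, so that the depth of each library is unknown and no counting interval is given. The sum of FPKM over genes is not a depth. It was 304269 ± 918 in the control, 340614 ± 12462 in the experimental and 338170 ± 11313 in the intervention group (mean ± SD, n = 3).

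The table has 33586 entries with 33516 distinct symbols. The 137 entries whose symbol occurs more than once were kept apart. Symbols were matched to GENCODE M21 (mm10) for gene identifiers and positions, and 96.8% of the entries had a match there. Genes with an FPKM of at least 1 in 3 or more of the 9 libraries were tested, which left 14570. Values were transformed as log2(FPKM + 1), and fold changes are on this scale, so that they lie closer to 1 than the ratio of FPKM for genes of low level. All 9 libraries entered 1 linear model with a mean per group (limma 3.58.1 with an intensity trend, in R 4.3.3, 6 residual and 3.53 prior degrees of freedom). Each of the 3 comparisons was tested two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Gene values are given as mean ± SD of FPKM over 3 libraries, and log2 fold changes as estimate ± SE. The labels do not say that replicates are separate animals, so that no p-value can be read as covering a spread between animals. Those of single genes measure only the spread between these samples. With 3 libraries against 3, an exact permutation test cannot give a p under 0.1, and this test (two-sided) was used only for values per library and for genes under the filter.

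In all, 40 gene lists of cell types and programs with 500 genes were fixed, and Ahsp, Il10 and Retnla had no entry. The 37 lists with 5 or more tested members were tested with camera (limma, correlation between genes set at 0.01) and adjusted over the lists within a comparison. Camera compares the genes of a list with the other genes, so that its p depends on this set correlation. Camera with a correlation estimated per list, and fry, a rotation test of whether the genes of a list move on balance one way, were run as alternatives. The estimated correlations ran from -0.0579 (hypoxia) to 0.952 (striatal markers), with 0.282 for interferon response and 0.498 for homeostatic microglia. Lists of cell types serve as marker groups in bulk tissue and do not count cells. Counts of a list are over its tested members. A gene low in control can pass the filter through a group where it is higher, while a low gene that stays level does not pass. The groups, the comparisons, the tests, the lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from those named in the closing section as chosen later. By that rule, the text names the 5 genes with the largest increase and the 5 with the largest decrease past the threshold in each comparison, among genes whose groups do not overlap. These genes also had a mean of at least 1 FPKM over the 9 libraries and no predicted-gene or clone name. If none passes, the text names the 3 with the smallest p in each direction under the same conditions. It also names up to 4 members of each list described, those with the smallest adjusted p, and in every comparison Hmox1, Il1b, Tnf, Gfap, Aqp4, Rbfox3, Hbb-bs, Ptbp1 and Ctdsp1. Other genes are said to be chosen after their values were seen. A few genes are not reported here.

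Sites for the miR-124 seed (GTGCCTT, TGCCTTA and GTGCCTTA) were searched in the annotated 3' UTRs of GENCODE M21. Of the tested genes, 12542 had a 3' UTR of at least 50 bases and 2028 were not searched. Genes with and without a site were compared by the difference of their median log2 fold change within 20 bins of 3' UTR length, with a permutation test of 100000 resamples and 100 shuffled seeds. For genes that rose in the experimental group, the kept share is the intervention minus control difference in FPKM as a percent of the experimental minus control difference. Comparisons that share a group were set against unchanged groups simulated with the same shared libraries (20 simulations). In these simulations no group differs and noise is drawn independently for each gene.

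The steps were tested on simulated data. With 14570 genes drawn from the real means and spread, 58.2%, 94% and 100% of log2 changes of 0.5, 1 and 2 were called with the right sign for experimental against control, 61.2%, 92.5% and 97% for intervention against experimental, and 53.7%, 95.5% and 98.5% for intervention against control. Each of these percentages rests on 66 or 67 changed genes. In these draws the groups differ only in the genes changed, and noise is independent for each gene. The adjusted threshold depends on how many genes change and by how much. The percentages therefore do not give the chance of calling such a change in the real comparisons. False calls made up 2.9%, 5.1% and 7.3% of the 173, 176 and 178 calls in these comparisons. Camera called 10 of 10 raised lists and 0 of 100 unchanged lists, with noise drawn independently for each gene, so that this test does not cover lists whose genes move together. A shift of -0.05 put into the genes with sites came back as -0.0499 over 12542 genes. Kept shares of 40% and 70% over 708 genes came back as 40.4% and 70.3%. Their mixtures were made from the same group means, so that this test does not cover the selection of genes on those libraries.

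The alternatives were other pseudocounts (0.1 and 5), no filter, a mean FPKM of at least 5, rescaling to TPM (each library to a sum of 1e6, which also lessens the weight of the pseudocount), median-of-ratios scaling, quantile normalization, robust hyperparameters, array weights, only the 6 libraries compared, the replicate number as a block, a fold of at least 2, and leaving out each library in turn. Added after the files were seen were a score of cortical minus striatal markers as a covariate, scaling on genes that are not mitochondrially encoded, the gene families of the closing section, genes selected without 1 experimental library, the kept share over every list raised in the experimental group, and seed sites matched also on the experimental minus control change. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, sites and figures.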

Results

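RNA sequencing measured gene expression in mouse brain in a model of intracerebral haemorrhage made with collagenase, an enzyme that breaks down vessel walls. The series places the tissue next to the haematoma. The 9 libraries fall into a control, an experimental and an intervention group of 3 libraries each. The title of the series names a tetrahedral nucleic acid carrier of miR-124, a microRNA abundant in neurons, as a treatment of the haemorrhage. The labels do not say what each group, the control included, received or when tissue was taken. Between 13408 and 14260 genes per library reached 1 FPKM, and the depth of the libraries is unknown. All 9 libraries had more than 5 FPKM of Y-linked Ddx3y and less than 0.1 FPKM of Xist, the RNA of the inactive X chromosome. On the main axis of variation, with 64.5% of the variance, the control libraries lay apart from the other 6, and each intervention library lay between the control and the experimental libraries.

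**Figure D1:**
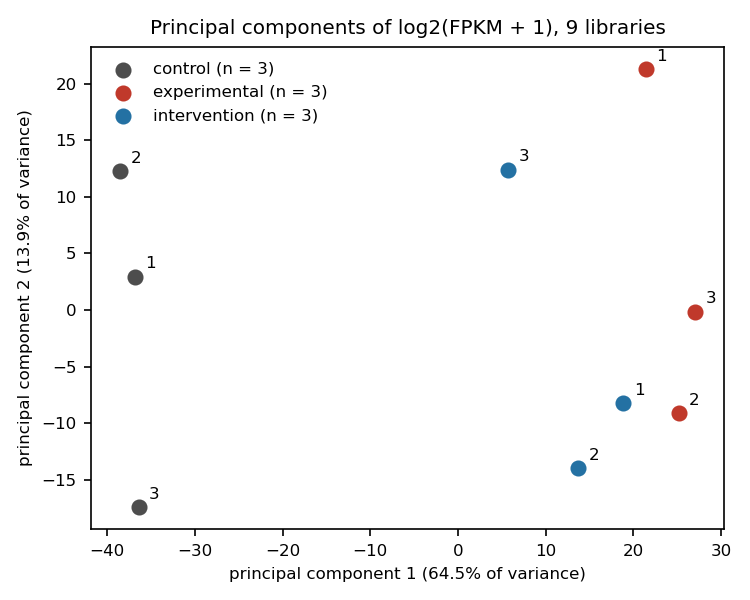
Principal components of log2(FPKM + 1) for the 9 libraries, as points coloured by group with the replicate number beside them; the axes give principal component 1 (64.5% of the variance) and principal component 2 (13.9%). The intervention libraries lie at 5.72, 13.69 and 18.86 on component 1, the experimental libraries at 21.41 to 27.02 and the control libraries at -38.55 to -36.42.

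The experimental and control groups were compared to ask which genes differ between them. Hmox1, which encodes the enzyme that breaks down heme, had the largest rise. Its level was 2.3 ± 0.326 FPKM in control and 321.6 ± 42.5 FPKM in experimental libraries (n = 3 each; log2 fold change 6.61 ± 0.13, 97.6-fold, adjusted p = 1.05e-08). Lyz2, the lysozyme of myeloid cells, rose from 6.34 ± 0.531 to 172.7 ± 12.1 FPKM (23.7-fold). Gfap, the filament protein of reactive astrocytes, rose from 37.9 ± 6.92 to 545.4 ± 150 FPKM (13.8-fold). Genes of neurons fell, among them Syp, a synaptic vesicle protein (log2 fold change -0.56 ± 0.07).

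The other largest rises were those of Tgm1, a transglutaminase (0.007 to 35.8 ± 10.8 FPKM, 35.4-fold), Lcn2, an iron-carrier binding protein of innate immunity (21.1-fold), and Serpina3n, a protease inhibitor of reactive astrocytes (18.7-fold). The largest falls were those of the activity-induced transcription factors Nr4a1 (-1.52 ± 0.33) and Egr1 (-1.24 ± 0.31), the vesicle calcium sensor Syt2 (-1.27 ± 0.12), the glutamate transporter Slc17a6 (-1.22 ± 0.31) and the prostaglandin D synthase Ptgds (-1.09 ± 0.20). Hmox1 lies on chromosome 8 at 75093621 to 75100589 (mm10, ENSMUSG00000005413.8), and Lyz2 on chromosome 10 at 117277331 to 117282321 (ENSMUSG00000069516.8). The libraries of the groups did not overlap in 55 of the 56 tested genes named for this comparison, a count that the rule for naming genes largely fixes. The exception was haemoglobin Hbb-bs, at 23.0 ± 12.8 FPKM in control and 13.98 ± 5.35 FPKM in experimental libraries (adjusted p = 0.179). The cytokine genes Il1b and Tnf lay under the filter. Il1b was at 0.0489 ± 0.0288 and 1.16 ± 0.4 FPKM, and Tnf at 0.0197 ± 0.0172 and 0.424 ± 0.0799 FPKM (exact permutation p = 0.1 for each, the smallest the design allows).

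**Figure D2:**
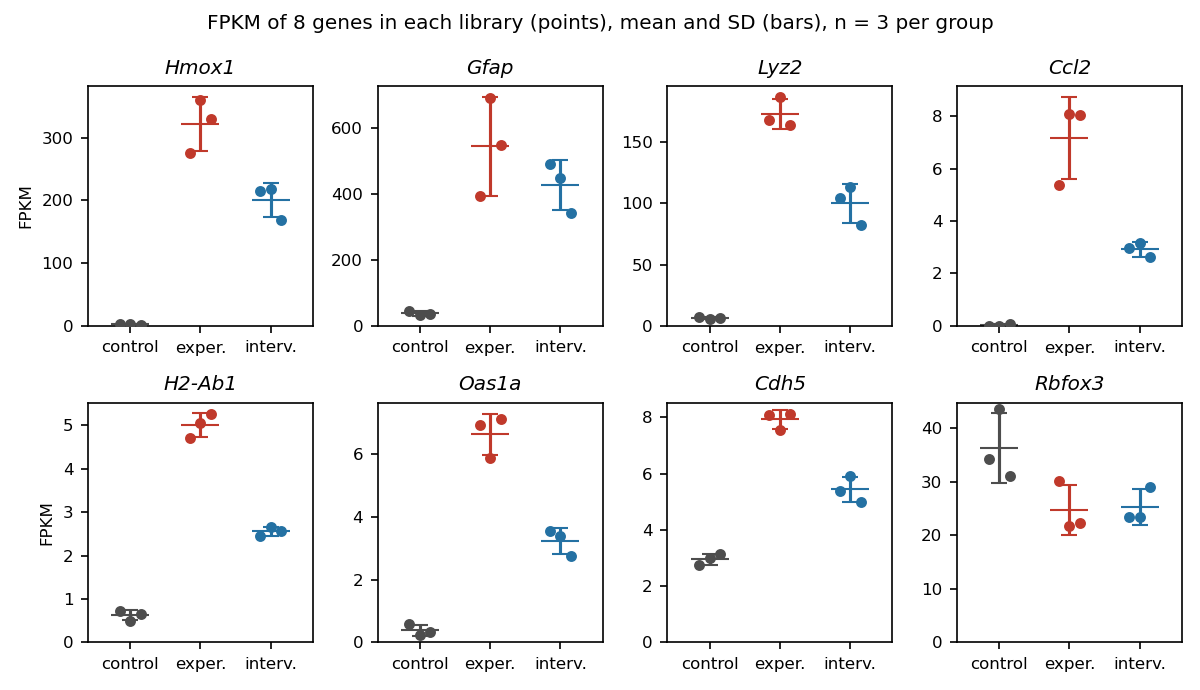
FPKM of 8 genes in each library (points) of the control, experimental (exper.) and intervention (interv.) groups, with the mean and SD as horizontal and vertical bars, n = 3 per group. Hmox1 had a mean of 2.3, 321.6 and 200.5 FPKM in the control, experimental and intervention group.

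Genes of microglia and macrophages rose together. All 14 markers of homeostatic microglia, such as the receptor gene Fcrls (10.5-fold), and all 17 genes of activated microglia and macrophages, such as the lysosomal Cd68 and the lectin Lgals3, were higher. Cd68 rose from 4.42 ± 0.882 to 71.3 ± 3.49 FPKM and Lgals3 17.6-fold. The list medians were 1.33 and 1.76 on the log2 scale (camera adjusted p = 2.55e-13 and 1.5e-14; adjusted p = 0.0659 for each with an estimated correlation). All 12 markers of infiltrating monocytes, such as Ms4a6c (6.97-fold), rose with a median of 1.53 (camera adjusted p = 5.62e-10; adjusted p = 0.0285 with an estimated correlation). So did all 9 tested genes of alternative macrophage activation, such as the scavenger receptor Msr1 (4.57-fold), with a median of 2.08 (adjusted p = 4.01e-10; adjusted p = 0.0278 with an estimated correlation). The member under the filter, Cd163, named after its values were seen, was level. It was at 0.4 ± 0.0622 FPKM in control and 0.393 ± 0.0782 FPKM in experimental libraries. Of neutrophil and lymphocyte markers only 4 and 3 reached the filter, and the lists were not tested. Of these 2 and 1 rose, among them Csf3r, a growth factor receptor of granulocytes (4.56-fold), and Cd79b, a B cell receptor component (1.78-fold), and the lowest log2 fold changes were -0.01 and -0.58. Of 12 neutrophil markers under the filter 7 had lower means in the experimental group and 5 higher, and of 13 lymphocyte markers 1 had a lower mean and 11 higher. Rescaled to TPM, the median of the monocyte markers was 2.38.

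Inflammatory programs rose as well. Of 9 cytokine and chemokine genes 7 rose, such as the monocyte attractants Ccl12 (0.300 ± 0.138 to 17.1 ± 1.62 FPKM) and Ccl2 (0.0304 ± 0.0527 to 7.16 ± 1.56 FPKM), with a median of 1.74 (camera adjusted p = 6.3e-07; adjusted p = 0.0642 with an estimated correlation). All 16 interferon response genes rose, such as Oas1a (5.54-fold) and Ifi27l2a (12.5-fold), with a median of 1.58 (adjusted p = 2.17e-13; adjusted p = 0.0642 with an estimated correlation). All 11 antigen presentation genes, such as the class II gene H2-Ab1 (3.71-fold), and all 10 complement genes, such as C1qb (7.97-fold) and the receptor C3ar1 (7.8-fold), rose with medians of 1.59 and 2.89 (adjusted p = 1e-10 and 1.47e-10; adjusted p = 0.0642 for each with an estimated correlation). Of Toll-like receptor and NF-kB genes 12 of 14 rose, such as Tlr2 (5.52-fold), and of nucleic acid sensors 12 of 13, such as Tlr7 (4.34-fold). Their medians were 0.76 and 0.81 (adjusted p = 4.2e-08 and 2.28e-07; adjusted p = 0.0503 and 0.0659 with an estimated correlation). Of inflammasome genes 5 of 6 rose, such as Gsdmd (2.86-fold), and of apoptosis genes 9 of 12, such as Casp8 (2.99-fold). Their medians were 0.95 and 0.57 (adjusted p = 0.000137 and 8.08e-06; adjusted p = 0.0998 and 0.116 with an estimated correlation). Rescaled to TPM, the medians of cytokines and inflammasome genes were 2.85 and 1.56.

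Glial, vascular and repair genes rose too. All 18 reactive astrocyte genes, such as Vim (11.4-fold), and 10 of 12 astrocyte markers, such as Aldh1l1 (2.31-fold) and the water channel Aqp4 (2.51-fold), were higher. Their medians were 1.47 and 0.61 (camera adjusted p = 2.55e-13 and 9.66e-06; adjusted p = 0.0642 and 0.0693 with an estimated correlation). All 12 endothelial markers rose, such as the junction genes Cldn5 (20.1 ± 1.4 to 58.4 ± 5.37 FPKM) and Cdh5 (2.26-fold), with a median of 0.71 (adjusted p = 6.09e-08; adjusted p = 0.0689 with an estimated correlation). Of pericyte markers 5 of 9 rose, such as Pdgfrb (1.49-fold), and of fibroblast and meningeal markers 7 of 8, such as Igfbp2 (4.08-fold). Their medians were 0.42 and 0.83 (adjusted p = 0.00305 and 0.000725; adjusted p = 0.101 and 0.0642 with an estimated correlation). Of matrix protease and plasminogen genes 10 of 11 rose, such as the inhibitor Timp1 (17.1-fold), with a median of 1.17 (adjusted p = 2.19e-07; adjusted p = 0.0278 with an estimated correlation). All 10 proliferation genes rose, such as Rrm2 (8.02-fold) and Birc5 (3.09-fold), with a median of 1.93 (adjusted p = 1.91e-09; adjusted p = 0.109 with an estimated correlation). Of oligodendrocyte precursor markers 6 of 9 rose, such as Gpr17 (1.71-fold), with a median of 0.43 (adjusted p = 0.00331; adjusted p = 0.177 with an estimated correlation). Of neurogenesis and repair genes 5 rose, such as the progenitor filament Nes (3.5-fold), and the growth factor Bdnf fell (log2 fold change -0.76 ± 0.16). The median of the 10 was 0.32 (adjusted p = 0.0422; adjusted p = 0.293 with an estimated correlation), and the call ended without control 2, experimental 2 or experimental 3 (adjusted p up to 0.0828). Rescaled to TPM, the median of the pericyte markers was 0.26.

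Genes of heme and iron handling rose in 8 of 12 cases and fell in 1. Besides Hmox1, the ferritin light chain Ftl1 (124.1 ± 5.82 to 823.1 ± 68.4 FPKM) and the iron exporter Slc40a1 (2.52-fold) rose. The median was 0.56 (camera adjusted p = 0.00112; adjusted p = 0.0642 with an estimated correlation). Of antioxidant and ferroptosis genes 7 of 13 rose, such as the transcription factor Nfe2l2 (2.53-fold), and 2 fell, with a median of 0.49 (adjusted p = 0.0123; adjusted p = 0.227 with an estimated correlation). Of 18 published miR-124 targets 16 rose, such as the myeloid transcription factor Cebpa (2.98-fold) and the splicing repressor Ptbp1 (6.83 ± 0.626 to 15.6 ± 1.16 FPKM), and the phosphatase Ctdsp1 rose 1.59-fold. Their median was 0.66 (adjusted p = 4.9e-09; adjusted p = 0.0693 with an estimated correlation). The 13 mitochondrially encoded transcripts, such as mt-Cytb (1.42-fold), had a median of 0.42 (adjusted p = 3.3e-05; adjusted p = 0.155 with an estimated correlation), which was 0.26 rescaled to TPM and turned to -0.02 with quantile normalization.

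Genes of neurons were lower. Of 14 neuronal markers 11 fell, with a median of -0.55 (camera adjusted p = 8.08e-06; adjusted p = 0.0642 with an estimated correlation). The neurofilament gene Nefh fell from 25.9 ± 3.98 to 11.9 ± 0.556 FPKM. Rbfox3, the NeuN gene, fell from 36.4 ± 6.51 to 24.7 ± 4.69 FPKM (log2 fold change -0.54 ± 0.16, adjusted p = 0.0231). Its call ended without control 2, experimental 2 or experimental 3 (adjusted p up to 0.0785). Of glutamate and GABA receptor genes 9 of 12 fell, and of interneuron markers 3 of 9, such as Gad1 (-0.83 ± 0.15). Their medians were -0.46 and -0.77 (adjusted p = 0.000503 and 0.0101; adjusted p = 0.174 and 0.116 with an estimated correlation). Of thalamic markers 3 of 8 fell, such as Slc17a6, with a median of -0.64 (adjusted p = 0.0312; adjusted p = 0.38 with an estimated correlation), and the call ended without control 1 or experimental 1 (adjusted p up to 0.0537). Of 14 striatal markers 0 passed in limma, while camera called the list lower with a median of -0.88 (adjusted p = 0.0278; adjusted p = 0.574 with an estimated correlation). This call ended without control 2, control 3 or experimental 1, with a median of -0.24 without experimental 1 (adjusted p = 0.284). The cortical minus striatal marker score ranged from -1.15 to 1.89 over the 9 libraries, and its group means did not differ beyond the spread (exact permutation p = 0.7, 1 and 0.8 for the 3 comparisons). Of heat shock and endoplasmic reticulum stress genes 4 of 11 fell, such as the asparagine synthetase Asns, a stress response gene (-0.70 ± 0.07), with a median of -0.22 (adjusted p = 0.0431; adjusted p = 0.299 with an estimated correlation). That call ended in 5 of the 9 runs with 1 library left out (adjusted p up to 0.0743), and the median was -0.11 without experimental 3, -0.14 without control 2 and -0.41 rescaled to TPM.

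The lists of cortical neurons (median -0.40), choroid plexus and ependyma (-0.15), mature oligodendrocytes (0.22), red blood cells (-0.61), immediate early genes (-0.50) and hypoxia (0.10, turned by rescaling to TPM) did not pass, with camera adjusted p from 0.0675 to 0.948. Rescaled to TPM, the medians were 0.06 for mature oligodendrocytes, -0.31 for choroid plexus and -0.76 for immediate early genes. For choroid plexus the test pointed up while the median and the mean were below 0. Of the immediate early genes 6 fell, and Atf3, a stress-induced transcription factor, rose 3.6-fold. In limma, 5415 of 14570 genes changed (37.2%), 2894 higher and 2521 lower, and 708 rose and 19 fell at least 2-fold. The libraries of the groups did not overlap in 7449 genes (51.1%, against 10% by chance). Camera called 31 of 37 lists, 25 up and 6 down. With an estimated correlation 3 remained, and fry called 30. Splits of the same libraries that mix the groups gave up to 30 lists with camera and 0 genes with limma. Such splits keep part of the group difference, so that their list counts do not measure false calls. Adjusted over the list alone, the counts of the lists were the same as over all genes tested, except for interneurons (4 lower), receptors (10 lower), mature oligodendrocytes (1 higher instead of 2), precursors (7 higher), pericytes (6 higher), apoptosis (10 higher) and hypoxia (2 lower instead of 1). Rescaling to TPM moved the median over all genes to -0.183, and 2175 genes were then higher and 4661 lower.

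**Figure D3:**
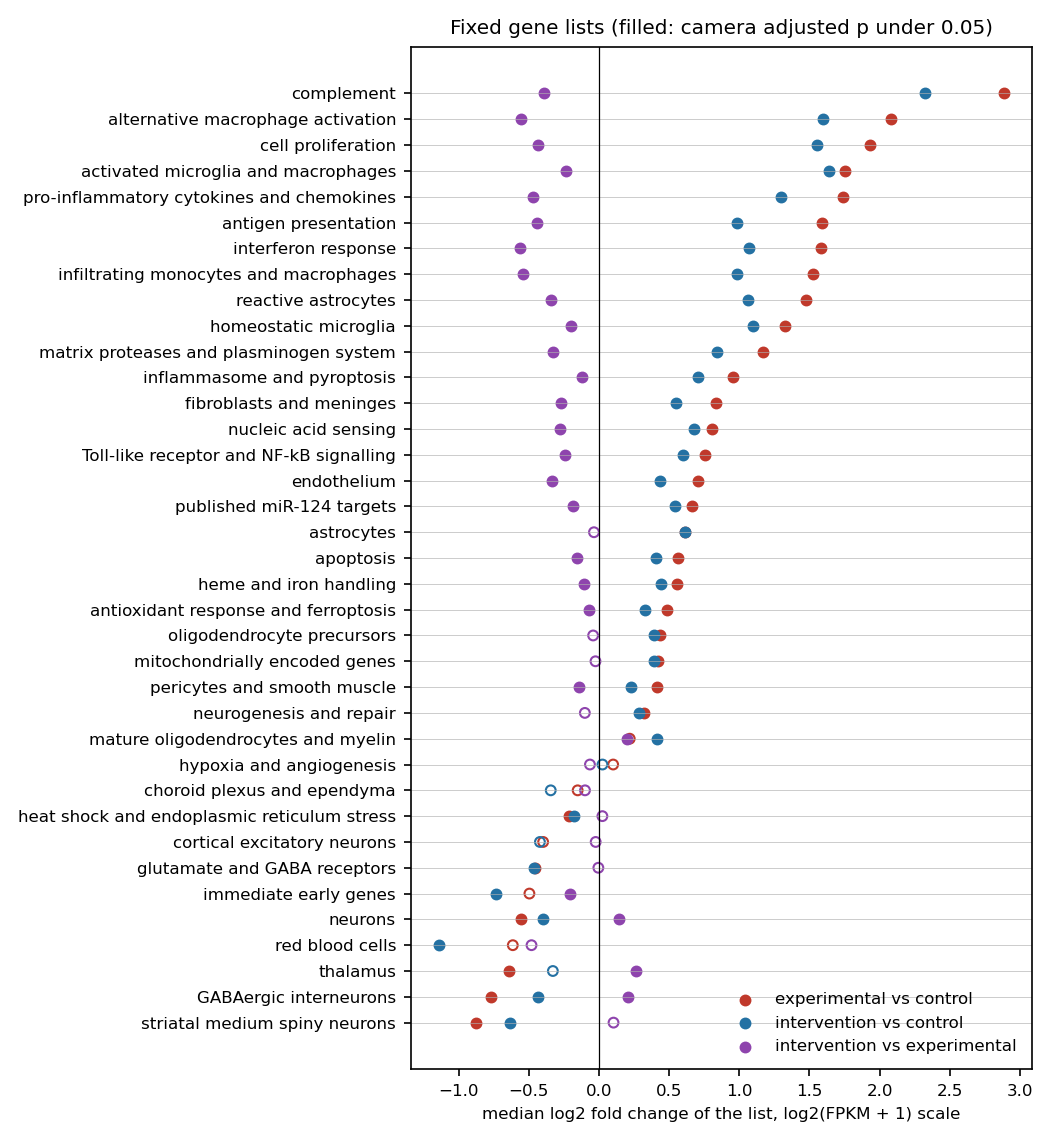
Median log2 fold change on the log2(FPKM + 1) scale of the 37 gene lists tested, for experimental against control (red), intervention against control (blue) and intervention against experimental (purple), with filled points where the camera adjusted p is under 0.05. Complement has the highest median, 2.89 in experimental against control, and mitochondrially encoded genes turn from 0.42 to -0.02 there with quantile normalization.

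The intervention and experimental groups were compared to ask whether expression differs with the intervention. No single gene passed in limma, while lists of interferon, antigen presentation and macrophage genes were lower in the intervention group as groups. All 16 interferon response genes had lower means, with a median of -0.56 (camera adjusted p = 2.92e-22; adjusted p = 0.0299 with an estimated correlation). Oas1a, a sensor of double-stranded RNA, was at 6.63 ± 0.654 FPKM in experimental and 3.23 ± 0.428 FPKM in intervention libraries (n = 3 each; log2 fold change -0.85 ± 0.12, adjusted p = 0.0615), and Irf7, a transcription factor of the interferon response, at 6.43 ± 0.916 and 3.81 ± 0.281 FPKM (adjusted p = 0.092). The chemokine gene Ccl2 was at 7.16 ± 1.56 and 2.93 ± 0.284 FPKM (-1.04 ± 0.14, adjusted p = 0.0615).

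The 11 antigen presentation genes were lower as a list, with a median of -0.44 (camera adjusted p = 3.26e-17; adjusted p = 0.0339 with an estimated correlation). The class II gene H2-Ab1 had the smallest p of all genes, at 5.01 ± 0.277 and 2.56 ± 0.099 FPKM (-0.76 ± 0.08, adjusted p = 0.0534). Another class II gene, H2-Eb1, was at 6.12 ± 0.402 and 2.88 ± 0.329 FPKM, and the invariant chain gene Cd74 at 17.9 ± 2.29 and 9.42 ± 1.42 FPKM. The 9 genes of alternative macrophage activation were lower with a median of -0.56 (adjusted p = 1.14e-14; adjusted p = 0.0177 with an estimated correlation), as for the scavenger receptors Msr1 (-0.60 ± 0.08, adjusted p = 0.0615) and Cd36 (-0.77 ± 0.16, adjusted p = 0.107). The 12 monocyte markers were lower with a median of -0.54 (adjusted p = 2.07e-12; adjusted p = 0.0224 with an estimated correlation). Ms4a6c was at 8.52 ± 1.25 and 4.77 ± 0.561 FPKM, and the clotting factor subunit F13a1 at 2.37 ± 0.0853 and 1.25 ± 0.162 FPKM. The 11 matrix protease and plasminogen genes were lower with a median of -0.33 (adjusted p = 7.31e-06; adjusted p = 0.0299 with an estimated correlation), as for Timp1 (-0.71 ± 0.15, adjusted p = 0.129) and fibronectin Fn1 (-0.60 ± 0.14, adjusted p = 0.139). Of these 5 lists, 16 of 16 interferon, 9 of 11 antigen presentation, 9 of 9 alternative activation, 9 of 12 monocyte and 5 of 11 protease genes passed when adjusted over the list alone, and 0 over all genes tested.

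Camera called further lists lower, and these calls were lost with an estimated correlation. Fry also lost activated microglia and macrophages (fry adjusted p = 0.0905), proliferation (0.0596) and antioxidant genes (0.1). It lost apoptosis (0.162), inflammasome (0.18) and immediate early genes (0.376) as well. The other lists of this paragraph stayed called with fry (adjusted p of at most 0.0431). The 12 endothelial markers had a median of -0.33 (camera adjusted p = 2.07e-12; adjusted p = 0.0526 with an estimated correlation). Cdh5 was at 7.92 ± 0.328 and 5.43 ± 0.456 FPKM and Cldn5 at 58.4 ± 5.37 and 42.5 ± 4.86 FPKM, and 10 passed when adjusted over the list alone. Cytokines and chemokines had a median of -0.47, as for Cxcl10, an attractant of T cells (-0.64 ± 0.14, adjusted p = 0.134), and Toll-like receptor and NF-kB genes -0.24 (adjusted p = 1.85e-08 and 3.55e-06; adjusted p = 0.0526 for each with an estimated correlation). Nucleic acid sensing (median -0.28), reactive astrocytes (-0.34), complement (-0.39), heme and iron handling (-0.10), fibroblasts (-0.27) and pericytes (-0.15) were lower with an adjusted p of at most 0.00422 (adjusted p from 0.0741 to 0.0907 with an estimated correlation). Homeostatic microglia (-0.20), activated microglia and macrophages (-0.23), proliferation (-0.43), antioxidant genes (-0.07), apoptosis (-0.15), inflammasome (-0.12) and immediate early genes (-0.20) were lower with an adjusted p of at most 0.0239 (adjusted p from 0.131 to 0.426 with an estimated correlation). In these lists Lgals3 was at 24.2 ± 2.51 and 12.8 ± 3 FPKM (-0.89 ± 0.15, adjusted p = 0.0784), and Gpnmb, a gene of lipid-laden macrophages, at 9.52 ± 1.28 and 5.56 ± 0.673 FPKM (adjusted p = 0.0677). The calls of antioxidant genes (without experimental 2, adjusted p = 0.096), apoptosis (without intervention 3, adjusted p = 0.126), inflammasome genes (without experimental 2, experimental 3, intervention 2 or intervention 3, adjusted p up to 0.163) and immediate early genes (without experimental 1 or intervention 2, adjusted p up to 0.181) ended with 1 library left out. Medians moved too. That of inflammasome genes was -0.06 without experimental 2 and -0.04 without intervention 3, against -0.18 and -0.24 without experimental 1 and intervention 1. Immediate early genes had -0.11 and -0.09 without experimental 1 and intervention 2, and antioxidant genes -0.15, -0.11 and -0.12 without experimental 1, experimental 3 and intervention 1 and -0.11 with quantile normalization. Without intervention 3 the medians were -0.09 for apoptosis, -0.24 for proliferation and -0.15 for activated microglia and macrophages. Without intervention 1 they were -0.17 for fibroblasts and -0.18 for heme and iron handling, and without experimental 1 -0.52 for reactive astrocytes. Adjusted over the list alone, the counts of lower genes were 6 of 9 cytokines, 5 of 14 Toll-like receptor genes, 8 of 13 sensors, 4 of 18 reactive astrocyte genes, 5 of 10 complement genes, 3 of 12 heme genes, 2 of 17 activated and 1 of 14 homeostatic microglia genes, 2 of 10 proliferation genes, 2 of 6 inflammasome genes and 1 of 9 pericyte genes, against 0 over all genes tested. No gene of the fibroblast, antioxidant, apoptosis and immediate early lists passed in this way.

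The 18 published miR-124 targets were lower as a list, with a median of -0.19. The camera adjusted p was 1.08e-07, or 0.103 with an estimated correlation, and the fry adjusted p was 0.0321. Of the targets, 7 passed when adjusted over the list alone and 0 over all genes tested. Cebpa was at 12.7 ± 0.65 and 9.66 ± 0.936 FPKM (-0.37 ± 0.08, adjusted p = 0.133), the lactate transporter Slc16a1 at 24.3 ± 2.52 and 18.4 ± 0.557 FPKM (adjusted p = 0.197). Ptbp1 was at 15.6 ± 1.16 and 12.1 ± 1.21 FPKM (adjusted p = 0.215), and Ctdsp1 had a log2 fold change of -0.06 (adjusted p = 0.928). Genes with a miR-124 seed site in the 3' UTR (3047 of 12542) differed in median by -0.0207 from genes without a site at matched 3' UTR length (permutation p = 1e-05, the smallest it can give). The permutation treats genes as replicates, which they are not, so that its p describes these libraries only. The same matched difference was 0.0868 in experimental against control and 0.0717 in intervention against control (permutation p = 1e-05 for each). Matched also on that experimental minus control change, a test chosen after the first result was seen, the difference was -0.0027 (permutation p = 0.278).

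Neuronal markers had a median of 0.15 (camera adjusted p = 0.000421; adjusted p = 0.0907 with an estimated correlation), and 1 of 14 passed when adjusted over the list alone. Nefh was at 11.9 ± 0.556 and 17.0 ± 0.756 FPKM (adjusted p = 0.129) and Syp at 125.5 ± 5.56 and 141.3 ± 1.69 FPKM (adjusted p = 0.451). Interneurons (median 0.21), thalamus (0.27) and mature oligodendrocytes (0.20) were higher as lists (adjusted p = 0.0239, 0.0471 and 0.00239; adjusted p = 0.191, 0.469 and 0.469 with an estimated correlation). These 3 calls ended with 1 library left out: interneurons without experimental 1 or intervention 1 (adjusted p up to 0.313), thalamus in 5 of 9 runs (up to 0.295) and oligodendrocytes without intervention 1 or intervention 3 (up to 0.259). Leaving out 1 library moved the median of thalamus from 0.27 to 0.18, 0.10 and 0.14 (without experimental 1, intervention 2 and intervention 3) and to 0.46 and 0.56 (without experimental 3 and intervention 1). That of oligodendrocytes moved to 0.09, 0.38 and 0.11 (without intervention 1, 2 and 3), that of interneurons to 0.32 without experimental 2 or experimental 3, and that of neurons to 0.08 without experimental 2 and to 0.10 with quantile normalization. Rbfox3 was at 24.7 ± 4.69 and 25.3 ± 3.3 FPKM (adjusted p = 0.978). Gfap was at 545.4 ± 150 and 428.7 ± 76.5 FPKM (adjusted p = 0.753), Aqp4 at 56.1 ± 12.3 and 44.6 ± 1.94 FPKM (adjusted p = 0.665). Hmox1 was at 321.6 ± 42.5 and 200.5 ± 27.5 FPKM (-0.68 ± 0.13, adjusted p = 0.101) and Hbb-bs at 13.98 ± 5.35 and 9.82 ± 0.961 FPKM (adjusted p = 0.823). Il1b was at 1.16 ± 0.4 and 0.433 ± 0.107 FPKM and Tnf at 0.424 ± 0.0799 and 0.404 ± 0.228 FPKM (exact permutation p = 0.1 and 0.9). The remaining lists did not pass (camera adjusted p from 0.138 to 0.984). For astrocytes the median was -0.04 while the mean and the test were above 0, for choroid plexus the median (-0.10) and the mean were below 0 while the test pointed up, and for receptors the median (-0.004) was below 0 while the mean and the test were above.

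With limma, 0 of 14570 genes passed between the intervention and experimental groups, against 1352 at an unadjusted p under 0.05 (417 higher and 935 lower). A split that sets experimental 1, experimental 3 and intervention 3 against the other libraries gave 1456, so that the real count is within what mixed groups give. The count was 76 with a pseudocount of 5 (3 higher and 73 lower), 35 with quantile normalization (all among the 76), and 1 with median-of-ratios scaling, H2-Ab1. Under the conditions for named genes, the smallest p among higher genes belonged to Etnppl, an astrocyte enzyme (4.82 ± 0.786 and 8.89 ± 0.553 FPKM, adjusted p = 0.0677), the kinase Sgk1 (adjusted p = 0.0741) and the synaptic organizer Cbln2 (adjusted p = 0.0852). Among lower genes it belonged to H2-Ab1, the metalloprotease Adam8 (6.86 ± 0.445 and 3.9 ± 0.385 FPKM, adjusted p = 0.0615) and Ccl2. The groups did not overlap in 1927 genes (13.2%, against 10% by chance). Among the 32 tested genes named here they did not overlap in 27, the exceptions being Aqp4, Ctdsp1, Gfap, Hbb-bs and Rbfox3. The rule for naming genes largely fixes that count. Camera called 26 of 37 lists, 4 up and 22 down, against 5 with an estimated correlation and 17 with fry. Splits that mix both groups gave up to 23 lists with camera. They keep part of the group difference, so that this count does not measure false calls. The drop from 26 to 5 lists with an estimated correlation shows that camera p-values overstate how sure the difference is where genes of a list move together.

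Genes that rose in the experimental group lay nearer to control in the intervention group. Of the 708 genes at least 2-fold higher in the experimental group, 98.9% had a lower mean in the intervention group, which kept a median of 67.1% of the difference from control (quartiles 60 and 75.3). These genes were selected with the same experimental libraries, which by itself moves them toward control. Selected without 1 experimental library and measured in it, the genes higher in the experimental group differed by -0.10, -0.19 and -0.20 (log2) between the intervention group and the library held out, and 73.3, 88.7 and 80.6% of them were lower in the intervention group. Over the 25 lists raised in the experimental group, the kept share was lowest for endothelium (48.6%) and interferon response (51.7%) and highest for astrocytes (89.1%) and mitochondrially encoded genes (92.9%), which were not lower as lists. The intervention libraries gave 40.1, 52.5 and 50.9% for endothelium, 102.6, 100.7 and 81.3% for astrocytes and 123.2, 74.7 and 91% for mitochondrially encoded genes. The order of the lists was not stable, since lists picked as highest and lowest without 1 replicate number differed by 26.9, 32.2 and -13.5 points in the libraries of that number. Libraries with the same number are not known to be paired, and the genes and lists were chosen with all 9 libraries. The covariance of the changes in experimental against control with those in intervention against experimental was -0.0575, against -0.00953 for unchanged groups that share the experimental libraries (difference -0.0479). The correlation across genes was -0.66. The simulated correlation of -0.50 holds only where no group differs, so that it sets no level for these data. No gene passed in limma in both with opposite signs, against 74 with a pseudocount of 5 and 34 with quantile normalization.

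**Figure D4:**
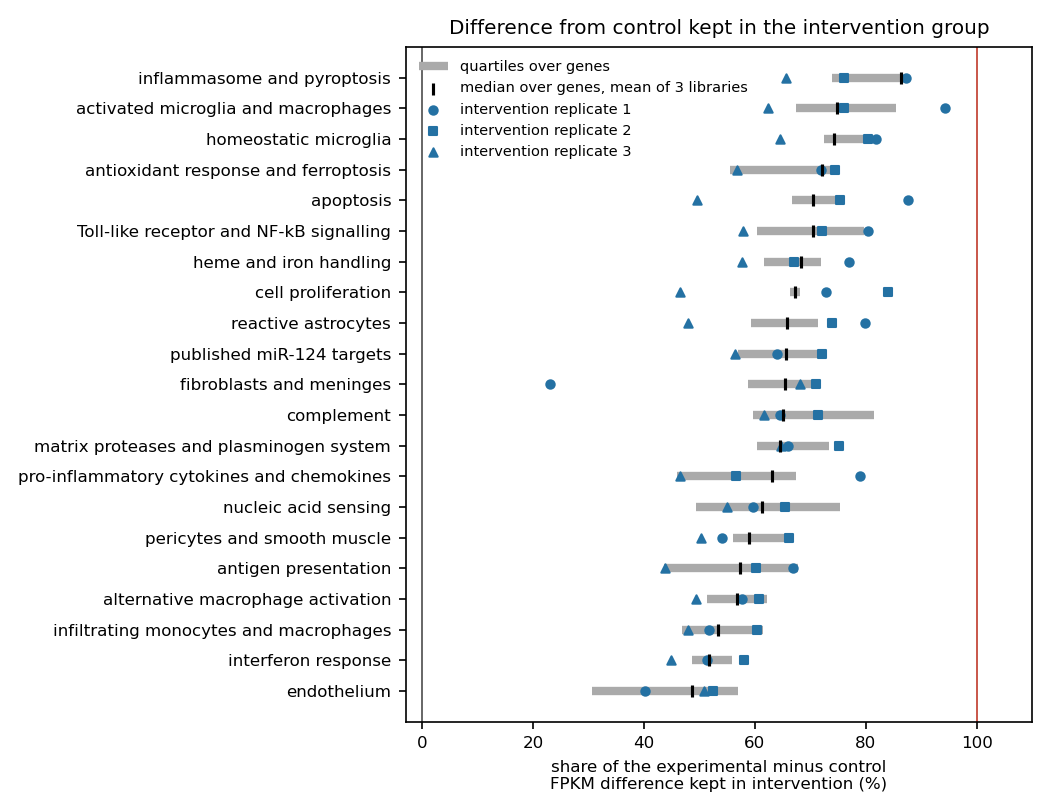
Share of the experimental minus control FPKM difference kept in the intervention group (%), for the genes called higher in the experimental group in the 21 raised lists that were lower in the intervention group; black ticks give the median over genes, grey bars the quartiles and blue symbols the median in each of the 3 intervention libraries. The medians run from 48.6% for endothelium to 86.4% for inflammasome genes, and for fibroblasts intervention replicate 1 lies at 23.0% against 71.0% and 68.1%.

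The intervention and control groups were compared to ask which differences from control are present in the intervention group. Hmox1 again had the largest rise, to 200.5 ± 27.5 FPKM from 2.3 ± 0.326 FPKM (n = 3 each; log2 fold change 5.93 ± 0.13, 60.9-fold, adjusted p = 2.93e-08), followed by Tgm1 (22.6-fold), Lcn2 (14.5-fold), Lyz2 (13.6-fold) and Serpina3n (13.5-fold). Gfap was 11-fold and Aqp4 2.04-fold higher, Ptbp1 1.67-fold and Ctdsp1 1.53-fold. The largest falls were those of Nr4a1 (-1.50 ± 0.33), Egr1 (-1.23 ± 0.31), haemoglobin Hbb-bt (-1.30 ± 0.42), the sodium channel subunit Scn4b (-1.19 ± 0.38) and B3gnt2, a sugar transferase (-1.62 ± 0.41, adjusted p = 0.0179). B3gnt2 was at 1.23, 7.17 and 1.35 FPKM in the 3 intervention libraries, and at 9.87 ± 1.86 FPKM in control. Hbb-bs fell from 23.0 ± 12.8 to 9.82 ± 0.961 FPKM (adjusted p = 0.0458) and Rbfox3 from 36.4 ± 6.51 to 25.3 ± 3.3 FPKM (adjusted p = 0.0412). The calls of 6 of these genes ended with 1 library left out. They were B3gnt2 (without control 2, intervention 1 or intervention 3, adjusted p up to 0.071), Egr1 (without control 1, control 2 or intervention 2, up to 0.0624), Hbb-bt and Hbb-bs (5 of 9 runs each, up to 0.151 and 0.129), Rbfox3 (5 of 9, up to 0.132) and Scn4b (6 of 9, up to 0.128). With all 9 libraries, robust hyperparameters also ended the calls of Hbb-bt (adjusted p = 0.0662), Scn4b (0.0614) and Hbb-bs (0.0603), and the cortical minus striatal covariate those of Hbb-bt (0.0502) and Hbb-bs (0.0511). Il1b was at 0.433 ± 0.107 and Tnf at 0.404 ± 0.228 FPKM in the intervention group, against 0.0489 ± 0.0288 and 0.0197 ± 0.0172 FPKM in control (exact permutation p = 0.1 for each).

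The lists moved in the same directions as in experimental against control. All 14 homeostatic and 17 activated microglia genes, such as Cd68 (10.2-fold), rose with medians of 1.10 and 1.64 (camera adjusted p = 5.5e-14 and 5.13e-16; adjusted p = 0.0547 for each with an estimated correlation). Monocyte markers (11 of 12, median 0.98), alternative activation (9 of 9, 1.60) and matrix protease genes (10 of 11, 0.84, such as Timp1, 10.5-fold) rose and kept their calls (camera adjusted p = 3.97e-09, 9.62e-10 and 3.17e-07; adjusted p = 0.0368, 0.0295 and 0.0295 with an estimated correlation). Complement (9 of 10, median 2.32, such as C1qb, 6.51-fold), interferon response (16 of 16, 1.07, such as Ifi27l2a, 7.25-fold), antigen presentation (11 of 11, 0.98, such as H2-Ab1, 2.19-fold), cytokines (7 of 9, 1.30, such as Ccl12, 9.6-fold), Toll-like receptor genes (11 of 14, 0.60), reactive astrocytes (17 of 18, 1.06), astrocytes (11 of 12, 0.61), heme and iron handling (7 higher and 1 lower of 12, 0.44, such as Ftl1, 4.76-fold) and fibroblasts (5 of 8, 0.55) rose (camera adjusted p of at most 0.00301; adjusted p = 0.0547 for each with an estimated correlation). Nucleic acid sensing (10 of 13, 0.68), published miR-124 targets (14 of 18, 0.55), inflammasome (5 of 6, 0.71), proliferation (10 of 10, 1.56), endothelium (7 of 12, 0.43, such as Cldn5, 2.06-fold), apoptosis (8 of 12, 0.40), precursors (5 of 9, 0.39), pericytes (4 of 9, 0.23), neurogenesis (4 higher and 1 lower of 10, 0.28), antioxidant genes (7 higher and 2 lower of 13, 0.33) and mature oligodendrocytes (4 of 12, 0.41, such as Mobp, 1.74-fold) rose (camera adjusted p of at most 0.0312; adjusted p from 0.0697 to 0.5 with an estimated correlation). So did the mitochondrially encoded genes (12 of 13, 0.39, turned to -0.02 with quantile normalization; camera adjusted p = 2.17e-05; adjusted p = 0.152 with an estimated correlation). Scaling moved several of these medians. Rescaled to TPM they were 1.70 for monocyte markers, 2.28 for cytokines, 1.21 for inflammasome genes and 2.41 for proliferation. They were 0.08 for pericytes, 0.26 for mature oligodendrocytes, 0.21 for antioxidant genes, 0.19 for neurogenesis and 0.24 for mitochondrially encoded genes, and quantile normalization gave 0.43 for inflammasome genes.

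Neuronal markers fell in 10 of 14 cases, such as Nefm (-0.81 ± 0.12), with a median of -0.40 (camera adjusted p = 1.06e-05; adjusted p = 0.0547 with an estimated correlation). Receptors (9 of 12, median -0.46), immediate early genes (8 lower and 1 higher of 12, -0.73, such as Fos, -0.94 ± 0.13), heat shock and endoplasmic reticulum stress genes (3 of 11, -0.18), interneurons (1 of 9, -0.43), striatal markers (0 of 14, -0.63) and red blood cell genes (4 of 5, -1.14) were lower as lists (adjusted p from 5.79e-05 to 0.0448; adjusted p from 0.136 to 0.532 with an estimated correlation). Several calls ended with 1 library left out. This held for interneurons (without control 2, intervention 2 or intervention 3, adjusted p up to 0.0827), striatal markers (without control 2, control 3, intervention 2 or intervention 3, up to 0.103) and red blood cell genes (without intervention 1 or intervention 2, up to 0.107). It also held for heat shock and endoplasmic reticulum stress genes (without intervention 3, 0.0892), neurogenesis (without control 2, 0.054), pericytes (without control 2 or intervention 2, up to 0.103) and mature oligodendrocytes (without control 3, intervention 1 or intervention 3, up to 0.103). The median of red blood cell genes was -0.72 without control 2, that of striatal markers -1.16 without control 1, and that of heat shock and endoplasmic reticulum stress genes -0.33 rescaled to TPM. Cortical neurons, thalamus, hypoxia and choroid plexus did not pass (adjusted p from 0.0557 to 0.92), and for choroid plexus the median (-0.34) and the mean were below 0 while the test pointed up. In limma, 4120 of 14570 genes changed (28.3%), 2461 higher and 1659 lower, and 2668 did without intervention 1. The groups did not overlap in 6424 genes (44.1%, against 10% by chance). They did not overlap in the 27 tested genes named here either, a count that the rule for naming genes largely fixes. Rescaling to TPM moved the median over all genes to -0.145 and the split to 1706 higher and 3622 lower, quantile normalization gave 2009 and 2041, and scaling on genes that are not mitochondrially encoded gave 2094 and 2288. Camera called 33 of 37 lists, 26 up and 7 down, against 3 with an estimated correlation and 30 with fry. Splits that mix the groups, and so keep part of their difference, gave up to 28 with camera.

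Adjusted over the list alone, the counts against control in the intervention group were the same as over all genes tested for 21 of the 37 lists and larger for the others, among them nucleic acid sensing (12), apoptosis (10), complement (10), endothelium (8), mature oligodendrocytes (7), precursors (7), published miR-124 targets (15) and neurons (11 lower). Of the genes called against control, 3779 were called with the same sign in the experimental and the intervention group (2277 higher and 1502 lower), against 489 and 287 for independent lists of these sizes. Simulated unchanged groups that share the control libraries gave 0. With no group differing, almost no gene can pass there, so that this 0 does not measure what sharing adds. The covariance of both sets of changes was 0.204, against 0.00976 simulated (difference 0.195). The correlation across genes was 0.95, and the simulated 0.51 again holds only where no group differs. The 3 control libraries cannot be split with at least 2 in each part, and part of the overlap may come from sharing them.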

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

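Between experimental and control 5415 genes changed, against 3354 with a mean FPKM of at least 5 (fewer genes tested, 7849), 727 at 2-fold or more, and 4292 to 5486 with 1 library left out. Between intervention and control 4120 changed, against 2606 (mean FPKM of at least 5), 474 (2-fold) and 2668 to 3950 (1 library left out, lowest without intervention 1). Between intervention and experimental 0 changed, against 76 with a pseudocount of 5, 35 with quantile normalization, 1 with median-of-ratios scaling (H2-Ab1), 1 with the cortical minus striatal covariate (Ccl2) and 0 to 1 with 1 library left out. Genes changed back numbered 0, against 74, 34, 1 and 1 in these settings and 0 to 1 with 1 library left out. With an estimated correlation 3, 5 and 3 lists were called in place of 31, 26 and 33, and fry called 30, 17 and 30. With 1 library left out the lists numbered 29 to 32, 23 to 27 and 30 to 34. With the replicate number as a block, 4702, 0 and 3251 genes and 31, 26 and 34 lists were called, and the block ended the calls of Rbfox3 in experimental against control (adjusted p = 0.0504) and in intervention against control (adjusted p = 0.0809). Correlations of residuals in libraries with the same number ran from -0.54 to 0.21, so that pairing was not assumed. The cause of these differences was not tested.

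Some directions that had not passed turned by the sign of the test, given here with their medians. Choroid plexus in experimental against control had -0.4413, -0.3629, -0.3092 and -0.1516 without control 3, experimental 2, experimental 3 and intervention 3 (range -0.4413 to 0.1657), and in intervention against control -0.5937 and -0.7955 without control 3 and intervention 3 (range -0.7955 to -0.0422). The rest concern intervention against experimental. Choroid plexus had -0.4309 and -0.4063 without experimental 1 and intervention 3 (up to 0.1134), and astrocytes -0.077 without experimental 1 (up to 0.021). Cortical neurons had -0.0395 with median-of-ratios scaling, 0.0352 with the covariate, and 0.2323, 0.0101 and 0.1439 without experimental 1, intervention 1 and intervention 2 (down to -0.2038). Striatal markers had -0.4322 and -0.0462 without experimental 1 and intervention 1 (up to 0.4633). Without experimental 1 both lists passed (camera adjusted p = 0.024 and 0.00138). Receptors had -0.0598 and -0.0708 without experimental 2 and intervention 3 (up to 0.1054). Mitochondrially encoded genes had 0.0391 and 0.0218 without experimental 1 and intervention 2 (down to -0.0598). Rbfox3 had -0.0376, -0.0206 and -0.0575 without experimental 2, experimental 3 and intervention 3 (up to 0.189), and Ctdsp1 0.0026 without intervention 3 (down to -0.1343).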

Other observations

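Gene families were also picked by symbol after the values were seen, some because their members had been seen to move, so that no test over a family is given. Counts are of genes past 0.05 in limma. In experimental against control, ribosomal protein genes were higher in 71 of 84 cases, such as Rplp0 (log2 fold change 1.09), with a median of 0.55. Cathepsins, the proteases of lysosomes, were higher in 9 of 11 cases, such as Ctsd (2.79) and Ctss (2.57), and all 4 Fc gamma receptors, which bind antibodies, were higher, such as Fcgr4 (2.58). Their medians were 1.42 and 2.52. All 6 guanylate-binding proteins, such as Gbp3 (1.70), and 11 of 21 collagens, such as Col4a1 (1.81), were higher, with medians of 0.95 and 0.56. With quantile normalization the median of collagens was 0.30. In intervention against experimental no member passed, and the medians were -0.43 for guanylate-binding proteins, -0.47 for Fc gamma receptors, -0.27 for cathepsins, -0.09 for ribosomal proteins and -0.07 for collagens.

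Members of families of neuronal excitability and vesicles fell in experimental against control. Potassium channel genes fell in 16 of 25 cases, such as Kcnc1 (-0.82), and sodium channel genes in 6 of 9, such as Scn1a (-1.01), with medians of -0.48 and -0.62. Genes of synaptic vesicles and their release fell in 21 of 32 cases, such as Sv2a (-0.63), and subunits of the vacuolar proton pump, which loads vesicles, in 13 of 19, such as Atp6v1d (-0.45), while 2 pump subunits rose. Their medians were -0.50 and -0.38. Cholesterol synthesis genes fell in 10 of 17 cases, and clock output genes in 6 of 12, such as Per2 (-0.51), with medians of -0.35 and -0.31. Rescaled to TPM these medians were -0.53 and -0.49. Proteasome subunits went both ways (5 higher and 4 lower of 41), and of nuclear complex I subunits 3 of 36 fell and of ATP synthase subunits 2 fell and 1 rose of 17. In intervention against experimental no member passed, and the medians were 0.13 for complex I, 0.10 each for the vesicle, pump and cholesterol families, 0.06 for ATP synthase, 0.05 and 0.04 for potassium and sodium channels, 0.04 for the proteasome and 0.01 for clock output genes. The last turned to -0.0015 with median-of-ratios scaling.

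Of 25 lists raised in the experimental group camera called 21 lower in the intervention group, of which 5 stayed called with an estimated correlation, and the test of uniform mixing was chosen after this was seen. A different share of cortex and striatum in the tissue might lower the 21, but with the marker score as a covariate their median was -0.2905 against -0.2787, and camera at the set correlation still called 21 (of which 16 had no call with an estimated correlation before the covariate), which argues against it as the whole cause. A single library might carry the pattern, but the weakest median with 1 library left out was -0.2421 (without intervention 3), which also argues against it for these lists. The medians of both tests are over lists picked as lower in these same libraries. This by itself favours values below 0, so that neither test can exclude its explanation. A smaller share of injured tissue in every intervention library could lower all raised lists alike. Over the 25 lists the held-out difference in kept share between the highest and lowest list was 15.2 points (SD 25 over 3 folds: 26.9, 32.2 and -13.5). The folds join libraries only by their number, and genes and lists were chosen with all libraries, so that they cannot decide. A smaller share of injured tissue stays open, and a treatment effect cannot be told apart from a smaller injury here.

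Camera called published miR-124 targets lower in the intervention group, with 0 of 18 targets past 0.05 over all genes. The camera call was lost with an estimated correlation (adjusted p = 0.103), and fry kept it (fry adjusted p = 0.0321). Genes with seed sites had a lower median too. The test of sites matched on the experimental minus control change was chosen after the first results. Repression of genes with sites could lower them, and 0 of 100 shuffled seeds gave a difference as low as that of the real seed at matched 3' UTR length, which met the criterion set beforehand. At matched 3' UTR length, the same genes lay higher than genes without a site in experimental against control (difference 0.0868). Matched on the experimental minus control change too, 31 of 100 shuffled seeds gave a difference as low (permutation p = 0.278), so that repression stays open. The targets may simply follow the genes that differ between experimental and control, since 21.53% of random lists matched on that change had a median as low as -0.1851.

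Mitochondrially encoded transcripts were higher in the experimental group, and the test of scaling was chosen after this was seen. Scaling between libraries may produce this, but scaled on the other genes the median was 0.362 (single transcripts 0.2874 to 0.4834) and rescaled to TPM 0.2623, against 0.4244, which argues against it as the whole cause. With quantile normalization the median was -0.0175, by construction, since these transcripts held ranks up to 26 in every library. Higher expression of the whole respiratory chain could raise them, but 53 nuclear-encoded subunits had a median of -0.0792, which argues against it. The cause was not tested further.

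Regrouping the libraries gave 10 splits per comparison, too few for a share under 0.05. Every split other than the real grouping keeps part of the group difference, so that its counts do not measure false calls alone. For genes, 1 of 10 splits (the real one) reached the 5415 of experimental against control (highest other 0), and 1 of 10 the 4120 of intervention against control (highest other 1). For intervention against experimental the real count was 0 (highest other 1), which 10 of 10 splits reach whatever the data, so that this count says nothing. At an unadjusted p under 0.05 its real count was 1352 (highest other 1456), and for its lists 1 of 10 reached 26 (highest other 23).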
